A study of Mus musculus with 10 samples.

How the data were processed

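RNA was measured in 10 libraries of primary mouse microglia treated with amyloid-β oligomers, 5 transfected with a negative control mimic and 5 with a miR-378a-3p mimic. Per the labels' protocols, poly(A) RNA was selected, fragmented and made into strand-marked libraries with dUTP, which were sequenced as paired reads on a NovaSeq instrument. The authors deposited 1 table with an estimated count and an FPKM value per gene and library, per the file headers. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used with the genome build GRCm39; the role and order of each tool, the versions of the last 2 and the annotation release are not given in the sources used here. The deposited expected counts were already whole numbers and were used as they stood. Low counts piled up at multiples of 4 (on average 933.5 genes per library had a count of 4, against 485.6 at 3 and 305.8 at 5), so 1 read pair was taken as worth about 4 counts. The deposited FPKM values are the authors' fragments per kilobase of gene model scaled to the library, and their scaling was kept as given. Whether strand was used in counting is not stated, so antisense and overlapping genes are uncertain. All 20 columns of values used matched a library by name, and 0 columns were left unmatched. Coordinates are those of the authors' table, and whether they are on the GRCm39 build of the notes or an earlier one was not checked.

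Each library's group came from the treatment label and its number from the title. The libraries held 48707985 to 65069571 counts. A floor of 3 read pairs, or 12 counts, is 0.184 to 0.246 CPM in these libraries; floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The test had been planned on FPKM, with a count test if counts were present; because the table holds counts, edgeR 4.0.16 (R 4.3.3) was the main test. Genes were kept by filterByExpr, scaled by TMM and fitted with glmQLFit and glmQLFTest, comparing the groups with no covariate; changes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Fold changes are mimic over control, and levels are means of FPKM with their SD over 5 libraries.

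The design, the named genes, the 32 gene lists and the first set of alternatives were fixed before the data were examined. The genes named are the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, mean FPKM of at least 1 and no overlap between the groups, passing over unnamed and pseudogene models (1 among the rises and 2 among the falls); up to 4 members with the smallest p from each described list; all measured reported targets of miR-378a-3p and Ppargc1b; and the 8 genes with an 8mer site and the largest falls. The rule gave 150 genes. They all stay in the counts, but some of them, 1 of which was among those with a single library far from the others, are not reported here. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. KEGG terms in the authors' annotation column with 15 to 300 tested genes were tested with camera at the preset and the estimated correlation, without fry.

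3' UTR sequences came from GENCODE M21, a GRCm38 annotation, joined by gene identifier and used for sequence only, with the longest 3' UTR of each gene; 21024 genes had one. For each library, the mean log2(FPKM + 1) of genes with a site minus that of genes without was compared between groups by an exact permutation test (scipy 1.17.1), with 2000 bootstrap draws over genes for the 95% interval. Control sequences were all permutations of the bases of the site, 630 heptamers and 1680 octamers, of which those without CpG and in at least 200 or 100 genes were used. An earlier form of the heptamer comparison, with a slightly different set of genes without the site, was seen before the one given.

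The alternatives were limma on log2(FPKM + 1), on a pseudocount of 0.1, on TPM and after quantile normalization, array weights, other filters, DESeq2 size factors, robust fitting, DESeq2 1.42.0, fold minimums of 1.5 and 2, a replicate block, and each library left out. Those on FPKM scale necessarily use limma. Added after seeing the data were limma on log2(FPKM + 1), a filter of mean FPKM of at least 1, counts divided by 4, library totals without TMM, and thinning to equal totals. The scripts were tested on simulated counts for mimic against control: of 66 genes changed 1.2-fold among 15619 tested, edgeR recovered 34.8%, of 67 changed 1.5-fold 61.2%, and of 66 changed 2-fold 77.3%, with 6 false calls. The list lowered in the simulation was called and 0 other lists were. The simulated genes were drawn independently of each other, so this does not test the preset correlation on genes that vary together. In a simulation of 9969 genes, a shift of -0.05 put on the genes with a seed site in the mimic libraries was recovered as -0.0495. The 4 lists with fewer than 5 measured members are given as counts only, and the epithelial list was compared with the lists of other cell types by Fisher's exact test.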

Results

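Poly(A) RNA of primary mouse microglia, the resident macrophages of the brain, was sequenced after the cells had been exposed to oligomers of amyloid-β, the peptide that forms plaques in Alzheimer's disease, and then transfected with a synthetic microRNA mimic. 5 libraries came from cells given a negative control mimic and 5 from cells given a mimic of miR-378a-3p. The series as a whole concerned exercise, vesicles released by skeletal muscle and plaque clearance by microglia, and the comparison asked how miR-378a-3p alters gene expression in amyloid-treated microglia. No library of cells without amyloid-β or without transfection was analysed here, so all changes are relative to amyloid-treated cells with the control mimic. The libraries held 48707985 to 65069571 deposited counts, at about 4 counts per read pair. Of 28247 genes in the table, 15916 had enough counts to be tested. Nothing in the labels states that the 5 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries only, which may be technical.

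The control and miR-378a-3p libraries separated completely. The first principal component of log2 CPM carried 56.2% of the variance. It placed the control libraries between -55.27 and -49.52 and the mimic libraries between 46.5 and 57.06. The second carried 7.21% and set mimic replicate 1 (-40.81) apart from the other mimic libraries. Pearson correlations of log2(FPKM + 1) across genes were 0.9896 to 0.9941 within groups and 0.9421 to 0.9552 between them, and genes are not independent replicates. With counts divided by 4, to put them on the scale of read pairs, the closest pair of libraries of a group had a chi-square of 2.67 per degree of freedom, so no pair was counted as the same library.

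**Figure D1:**
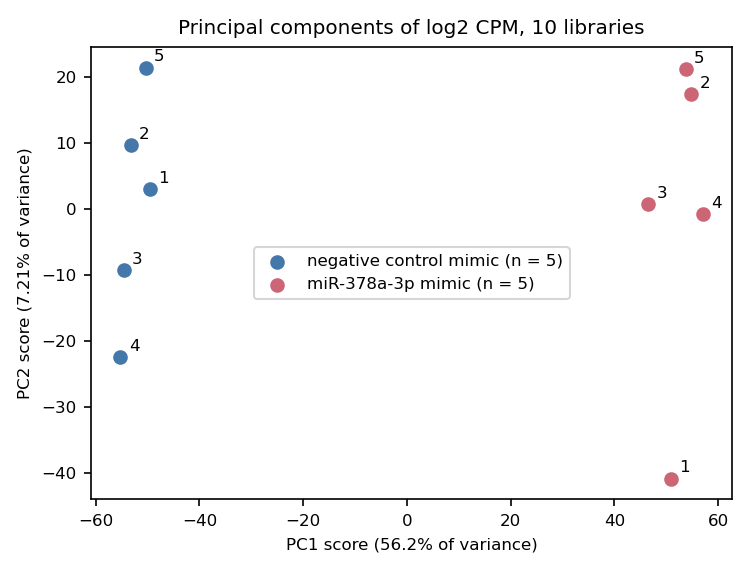
Scores of the 10 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis (56.2% and 7.21%), points coloured by group and numbered by replicate. All 5 mimic libraries lie on the right and all 5 control libraries on the left, and mimic replicate 1 lies lowest on the second component.

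With the mimic, the chemokine receptor gene Cx3cr1, the growth factor gene Igf1 and the genes of arginase 1 and inducible nitric oxide synthase were among the 10 genes with the largest falls. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484 in the deposited coordinates), which competes for arginine and marks alternatively activated macrophages, fell from 18.9 ± 1.79 to 0.209 ± 0.17 FPKM (SD, n = 5 each). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), which makes nitric oxide from the same amino acid, fell from 24.8 ± 1.76 to 1.12 ± 0.297 FPKM. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120068296), the fractalkine receptor, fell from 28.6 ± 1.84 to 0.475 ± 0.111 FPKM, a log2 fold change of -6.00 (SE 0.107, edgeR quasi-likelihood adjusted p = 5.55e-15). Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042), a growth factor secreted by activated microglia, fell from 11.4 ± 0.958 to 0.437 ± 0.15 FPKM. The other largest falls were in Gpr34, Serpinb1a, Odf3l1, Siglec1, Gpr183 and Hp, with log2 fold changes between -5.80 and -3.94. The mimic libraries held between 0 and 0.147 FPKM of Gpr34 and between 0 and 0.345 FPKM of Arg1, so these folds rest on few read pairs and their exact size is uncertain.

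The largest rises were in genes of low expression in control cells. Eml1 (ENSMUSG00000058070, chromosome 12, 108370957 to 108539617), a microtubule-associated protein, rose from 0.0708 ± 0.0185 to 2.53 ± 0.187 FPKM, a log2 fold change of 5.05 (SE 0.138, edgeR adjusted p = 2.74e-13). Cxcr3, the receptor for the interferon-induced chemokines, rose from 0.373 ± 0.132 to 6.05 ± 0.339 FPKM. Dmpk, Chpf and Nckap1, a subunit of the WAVE complex that drives actin branching, rose by 3.53, 3.41 and 3.36 on the log2 scale. Nr4a2, an orphan nuclear receptor, rose by 2.90. The histone genes Hist1h4m and H2ac7 rose by 3.36 and 2.93, but histone genes have near-identical copies and their counts are uncertain. Epha2 and Sfn complete the 10 largest rises. Mimic replicate 1, which held 93 genes hardly seen in the other libraries, had the highest Epha2 (3.69 FPKM) and Sfn (4.10 FPKM) values, and without it their log2 fold changes were 3.72 and 2.42 in place of 3.87 and 2.97, both still past the edgeR threshold.

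**Figure D2:**
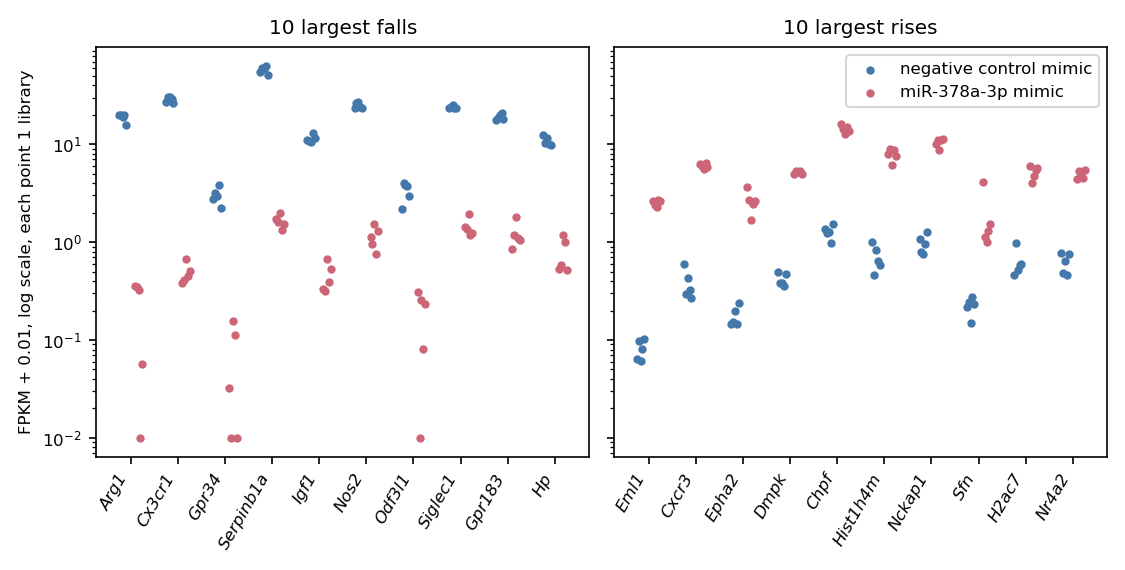
FPKM plus 0.01 on a log axis for the 10 genes with the largest falls (left) and the 10 with the largest rises (right), each point 1 library, blue for the negative control mimic and red for the miR-378a-3p mimic (n = 5 each). The groups do not overlap for any of the 20 genes, which the rule that chose them required. Arg1, Gpr34 and Odf3l1 each had a mimic library at 0.

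In all, 10056 of the 15916 tested genes (63.2%) passed an adjusted p of 0.05, 5050 higher and 5006 lower with the mimic. The median absolute log2 fold change of these genes was 0.488. A change of at least 2-fold was found for 765 genes that rose and 1346 that fell, and of at least 4-fold for 188 and 403. In 8309 tested genes (52.2%) the 5 libraries of one group lay entirely above those of the other, against 0.794% by chance. The share of changed genes that were higher was 50.2%. With library totals in place of TMM it was 58.4% (5937 higher and 4225 lower), so the balance of directions depended on the scaling. With limma on log2(FPKM + 1), which differs in test, unit and filter as well, it was 62.1% (5348 higher and 3258 lower).

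Of 32 gene lists fixed before the data were examined, 28 had 5 or more measured members and were tested with camera at a preset inter-gene correlation of 0.01. After adjustment 13 were lower with the mimic and 2 higher. Some lists share members, such as Fabp5 and Lpl in those of disease-associated microglia and of lipid efflux and droplets, so the calls are not independent. With correlations estimated from the data, 3 lists passed, those of disease-associated microglia, phagocytic receptors and the type I interferon response. Other splits of the same 10 libraries called a median of 6 lists and up to 14 with the preset correlation, and 0 with the estimated one. No split into 5 and 5 balances the groups, so these splits keep part of the group difference. The median was 11 lists in 20 splits with 4 libraries of one group on one side and 5 in 79 splits with 3.

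Genes of the disease-associated state, which microglia adopt around plaques, fell together. Of 26 measured members 20 fell, 4 rose and 2 did not pass, with the same numbers adjusted over the list alone. The median log2 fold change was -0.96 (camera adjusted p = 1.12e-22, and adjusted p = 0.0335 with an estimated correlation). The glycoprotein Gpnmb fell from 883 ± 31.3 to 314 ± 7.9 FPKM, the fatty acid binding protein Fabp5 from 153 ± 4.82 to 47.2 ± 2.82, the lipoprotein lipase Lpl from 145 ± 9.6 to 38.2 ± 2.48 and the cystatin Cst7 from 69.1 ± 2.17 to 12.7 ± 1.47 (SD, n = 5 each). Axl, a receptor on the list that did not pass (edgeR adjusted p = 0.36) and was singled out after its values were seen, was at 0.378 ± 0.0627 FPKM in control libraries and 0.992 ± 2.16 in mimic libraries. Mimic replicate 1 held it at 26.79 CPM, against a mean of 0.151 CPM in the other mimic libraries and 2.13 CPM in control libraries. Without mimic replicate 1 the log2 fold change of Axl was -3.88 in place of 1.27 (edgeR adjusted p = 2.68e-07, up to 0.737 over the alternatives). The list then held 21 genes that fell and 3 that rose. Homeostatic genes fell as well, 11 of 14, with 1 that rose and 2 that did not pass, and the same numbers adjusted over the list alone. Their median was -1.01 (camera adjusted p = 5.74e-09, adjusted p = 0.063 with an estimated correlation). Besides Cx3cr1, the survival receptor Csf1r fell from 58.9 ± 1.13 to 35.2 ± 1.7 FPKM and the lipid receptor Trem2 from 29.9 ± 1.57 to 13.1 ± 1.13. Tmem119 and P2ry12, chosen after their values were seen, were at 0.69 and 1.49 FPKM in control libraries and fell by 1.18 and 2.58 on the log2 scale.

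Phagocytic receptors and engulfment genes were lower, with 23 of 31 falling, 1 rising and 7 not passing (24 falling and 1 rising adjusted over the list alone). Their median was -0.52 (camera adjusted p = 1.47e-07, adjusted p = 0.0275 with an estimated correlation). Sirpa, which inhibits engulfment on binding CD47, fell from 127 ± 1.7 to 52.7 ± 2.87 FPKM. The scavenger receptor Msr1 fell from 4.37 ± 0.247 to 1.54 ± 0.0735 and Plcg2, a signalling enzyme below Trem2, from 90.8 ± 1.76 to 61.7 ± 2.07. Of the 8 measured enzymes that degrade amyloid-β, 3 fell, 2 rose and 3 did not pass (4 fell and 2 rose adjusted over the list alone). The median was -0.32 (camera adjusted p = 0.0379, adjusted p = 0.121 with an estimated correlation). It was -0.113 with limma on log2(FPKM + 1) and -0.153 after quantile normalization. The call of the list ended in 8 of 26 alternatives. The adjusted p ran from 2.45e-08 with fry, which does not compare a list with other genes, to 0.495 with camera after quantile normalization. Without mimic replicate 1, 5 of the 8 fell. The number that rose was 1 without control replicate 3 or mimic replicate 2. Plau, urokinase, fell from 148 ± 6.98 to 30.8 ± 3.72 FPKM, Ctsb, cathepsin B, from 579 ± 14.4 to 361 ± 5.06, and Nln, neurolysin, by 0.22 on the log2 scale. Ece1, endothelin converting enzyme, rose from 12.5 ± 0.256 to 18.6 ± 1. Lysosomal genes went both ways, 16 falling and 10 rising of 32, with the same numbers adjusted over the list alone (camera adjusted p = 0.0879). The median was -0.0619, and 0.0286 with limma on log2(FPKM + 1). Ctss, cathepsin S, and Tfeb, a transcription factor for lysosomal genes, fell by 0.80 and 2.05 on the log2 scale, and the sialidase Neu1 rose by 0.91. The autophagy list was not called (11 rose and 8 fell of 26, camera adjusted p = 0.166). The kinases Ulk1 and Ulk2 rose by 1.36 and 0.71 and Atg9a by 0.91, and Atg13 fell by 1.09.

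**Figure D3:**
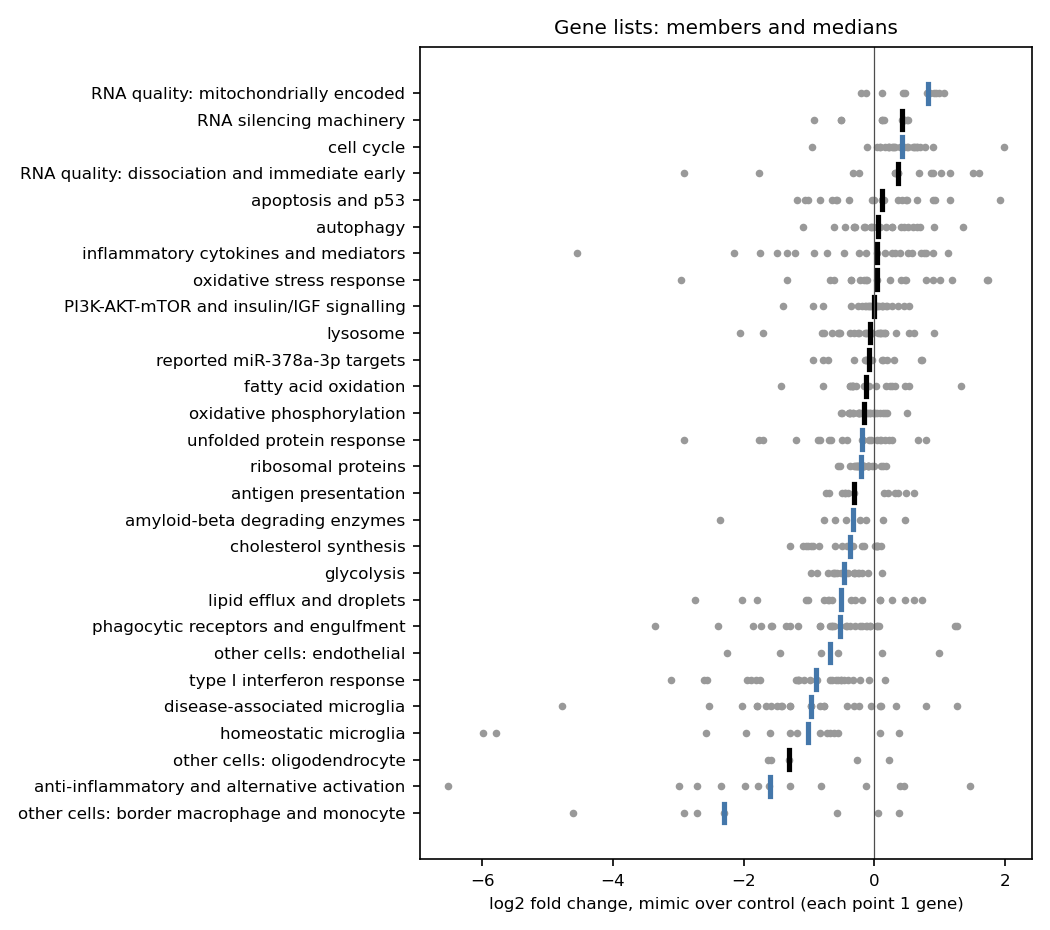
Log2 fold change (mimic over control) of every measured member of the 28 tested gene lists, each grey point 1 gene, with the list median as a bar, blue where camera with the preset correlation passed after adjustment and black where it did not. The lists of disease-associated (median -0.96) and homeostatic microglia (-1.01) and of interferon genes (-0.90) lie to the left, and those of mitochondrially encoded (0.82) and cell cycle genes (0.42) to the right.

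Type I interferon response genes fell, 24 of 27, with 1 that rose and 2 that did not pass, and the same numbers adjusted over the list alone. The median was -0.90 (camera adjusted p = 4.33e-09, adjusted p = 0.00324 with an estimated correlation). Oasl2 and Oas1a, members of the oligoadenylate synthetase family, fell by 2.60 and 1.16 on the log2 scale, Irf9, a part of the interferon-activated transcription factor, by 0.89 and the antiviral membrane protein Bst2 by 0.87. The number of interferon genes that rose was 0 without control replicate 1, 2 or 3 or mimic replicate 4 or 5. The Oas genes are close paralogs, and their counts are uncertain. Markers of alternative activation fell in 10 of 13 and rose in 3, with the same numbers adjusted over the list alone. The median was -1.6 (camera adjusted p = 0.00074, adjusted p = 0.063 with an estimated correlation). Among genes with a mean FPKM of at least 5 the camera adjusted p was 0.181, the highest of a range from 7.05e-09 with fry. The lectins Mgl2, Clec10a and Mrc1 fell by 1.98, 1.77 and 2.72, and the interleukin 1 receptor antagonist Il1rn by 1.60, and Mgl2 and Clec10a are paralogs. Inflammatory mediators split evenly, 9 rising and 9 falling of 23, with the same numbers adjusted over the list alone (camera adjusted p = 0.44). The median was 0.0512 and the mean -0.36. Icam1 rose from 14.6 ± 0.287 to 27.2 ± 0.904 FPKM. The chemokine Ccl3 fell from 823 ± 28.3 to 463 ± 38.1 and Tnfaip3, an inhibitor of NF-κB signalling, from 4.19 ± 0.226 to 1.01 ± 0.14. Antigen presentation genes also split, 6 rising and 7 falling of 13, with the same numbers adjusted over the list alone (camera adjusted p = 0.619). Cd74 and H2-D1 rose by 0.49 and 0.37, and Psmb8 and H2-T23 fell by 0.73 and 0.44. H2-D1 and H2-T23 belong to a family of similar genes and are uncertain.

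Metabolic genes were lower in several lists. Of 21 glycolysis genes 18 fell and 1 rose, with the same numbers adjusted over the list alone (median -0.46, camera adjusted p = 3.66e-08, adjusted p = 0.189 with an estimated correlation). Hk2, hexokinase 2, fell from 33.1 ± 1.24 to 19.1 ± 0.991 FPKM, Eno1 from 730 ± 25.2 to 513 ± 9.5 and Bnip3, a mitophagy receptor induced by hypoxia, from 221 ± 10.1 to 120 ± 4.29. Of 21 cholesterol synthesis genes 14 fell and 1 rose (median -0.37, camera adjusted p = 9.34e-07, adjusted p = 0.11 with an estimated correlation). The number that rose was 0 without control replicate 1, 2, 3 or 4 or mimic replicate 2, 3 or 4. Fdft1, Nsdhl, Fdps and Hmgcs1 fell by 1.05, 1.29, 0.84 and 1.01 on the log2 scale. Lipid efflux and droplet genes fell in 11 of 18 and rose in 4 (median -0.50, camera adjusted p = 1.56e-06, adjusted p = 0.063 with an estimated correlation). Fabp4 fell from 58.2 ± 1.4 to 9.25 ± 0.764 FPKM and the droplet protein Plin2 from 61.9 ± 2.4 to 32.7 ± 1.96. Oxidative phosphorylation (18 fell and 5 rose of 31, camera adjusted p = 0.0714) and fatty acid oxidation (10 fell and 7 rose of 21, camera adjusted p = 0.949) were not called. Of the oxidative phosphorylation genes 3 rose and 18 to 20 fell without control replicate 1, 2, 4 or 5 or mimic replicate 1 or 2. Sdha, Sdhc and Uqcrc1 fell by 0.50, 0.37 and 0.37, and Cycs rose by 0.50. Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 2.42 ± 0.119 to 6.49 ± 0.199 FPKM while Echs1 and Etfa fell by 0.78 and 0.34 and Acadvl rose by 0.47. Counts adjusted over the list alone were the same for cholesterol synthesis, lipid and autophagy genes. For oxidative phosphorylation 19 fell and for fatty acid oxidation 11 fell.

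Cell cycle genes rose, 24 of 28, with 1 that fell and 3 that did not pass, and the same numbers adjusted over the list alone. The median was 0.42 (camera adjusted p = 5.52e-07, adjusted p = 0.332 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 12.3 ± 1.74 to 52.0 ± 2.73 FPKM, Pcna from 103 ± 2.46 to 173 ± 3.65 and the replication helicase gene Mcm4 from 24.7 ± 1.47 to 49.4 ± 2.18. The mitotic cyclin Ccnb2 fell from 57.5 ± 1.1 to 31.6 ± 2.5. Apoptosis and p53 genes went both ways (12 rose and 8 fell of 23, camera adjusted p = 0.949). Bcl2l11, which promotes death, rose by 0.66, and Bcl2l1, which opposes it, and Cdkn1a fell by 1.18 and 0.82. Unfolded protein response genes fell in 12 of 22 (13 adjusted over the list alone) and rose in 7 (median -0.18, camera adjusted p = 0.00538, adjusted p = 0.189 with an estimated correlation). Their call ended in 6 of 26 alternatives, with adjusted p from 1.92e-07 with fry, which does not compare a list with other genes, to 0.189. The number that rose was 3 without control replicate 2 and 4 without control replicate 3, with 13 falling each time. Atf3 fell from 62.7 ± 1.48 to 8.88 ± 1.42 FPKM and Atf4 and Xbp1 by 0.86 and 0.82 on the log2 scale, while Hyou1 rose by 0.80. The oxidative stress list split, 10 rising and 10 falling of 21 (camera adjusted p = 0.588). The reductases Srxn1 and Txnrd1 rose by 1.73 and 1.01, and Cybb and Ncf1, subunits of the phagocyte NADPH oxidase, fell by 2.96 and 1.33. PI3K, AKT, mTOR and insulin signalling genes (9 rose and 7 fell of 27, camera adjusted p = 0.478) included Pik3cb, Pik3r5 and Grb2, with log2 fold changes of -1.39, -0.93 and -0.78, and Pdpk1, with 0.46. The median of this list was -0.00321, and 0.0838 with limma on log2(FPKM + 1). RNA silencing genes (10 rose and 3 fell of 13, camera adjusted p = 0.183) included a fall of Ago2 from 45.8 ± 1.58 to 25.7 ± 1.28 FPKM and rises of Tnrc6b, Dicer1 and Tnrc6c by 0.46, 0.45 and 0.50. Adjusted over the list alone the apoptosis, oxidative stress, signalling and RNA silencing lists gave the same numbers.

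Whether the transfected miRNA acted through its seed was tested in 9969 genes with an annotated 3' UTR and a mean FPKM of at least 1. The 1842 genes with a 7mer or 8mer match (AGTCCAG or GTCCAGA) had a mean log2 fold change of 0.078 on the log2(FPKM + 1) scale, against 0.053 in 6799 genes without the 6mer GTCCAG. The difference of 0.0248 was in the direction opposite to repression (exact two-sided permutation test of 5 against 5 libraries, p = 0.0159, 0.0318 adjusted over 6 site classes, 95% bootstrap interval over genes 0.00165 to 0.0483). Adjusted for 3' UTR length and GC content the difference was 0.00461 (exact p = 0.143). The 322 genes with the 8mer AGTCCAGA were lower than genes without a site by a difference of -0.0179 (exact p = 0.0476, adjusted 0.0476, interval -0.0739 to 0.0371). After adjustment for length and GC it was -0.0429 (exact p = 0.00794, the smallest that 5 against 5 can give). That adjustment and the octamer comparison were added after the result for the 8mer was seen, and the octamer comparison was made without the adjustment. The 7mer-m8 and 7mer-A1 classes were higher by 0.0434 and 0.0189, and the 6mer class by 0.0401 (exact p = 0.00794 for the 6mer). Genes with a match to the other strand, miR-378a-5p (GTCAGGA), were higher by 0.0275 (exact p = 0.0318). The permutation test measures the spread between libraries and not between genes, and all 6 classes passed it. Its p-values therefore do not set the sites of miR-378a-3p apart from other sites. Genes with a 7mer or 8mer site fell in 34.7% of cases and genes without a site in 36.5% (Fisher's exact test p = 0.163, adjusted 0.327). Among 300 heptamers made of the same bases, without CpG and present in at least 200 genes, 198 had a difference as low as that of AGTCCAG or lower. Among 890 octamers made of the bases of the 8mer, without CpG and present in at least 100 genes, 91 had a difference as low as that of the 8mer or lower.

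**Figure D4:**
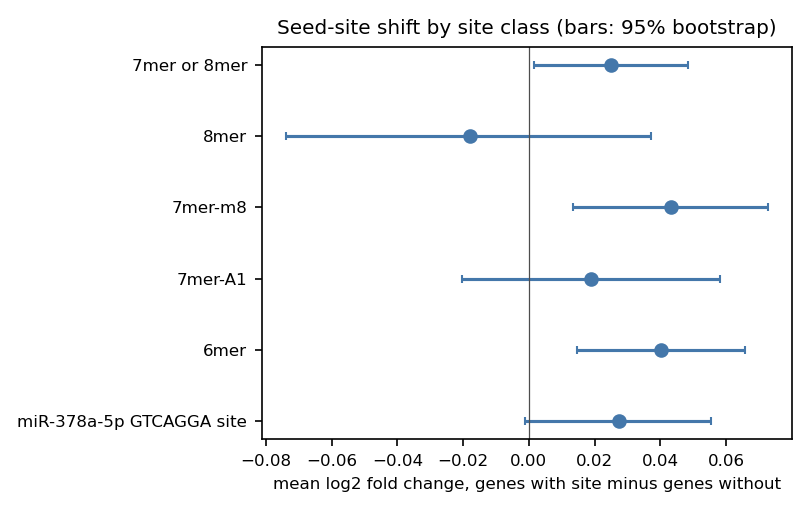
Difference in mean log2 fold change between genes with and without each kind of seed match, with 95% bootstrap intervals over genes (x axis, log2 scale). The 8mer class lies below 0 (-0.0179) and the other classes lie above it. The intervals of the 8mer, 7mer-A1 and miR-378a-5p classes span 0.

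Of the 14 measured reported targets of miR-378a-3p, 6 fell, 5 rose and 3 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.478). The median was -0.08, and 0.0168 with limma on log2(FPKM + 1). Vegfa fell from 21.5 ± 1 to 11.9 ± 0.492 FPKM, Grb2 from 59.2 ± 2.24 to 36.7 ± 1.18 and Pdk1 from 48.3 ± 1.55 to 31.5 ± 1.43. Atg12, Igf1r and Crat fell by 0.31, 0.13 and 0.12 on the log2 scale. Grb2, Pdk1, Igf1r and Crat carry an 8mer site in the 3' UTR, and Vegfa and Atg12 carry no 6mer match there. Akt1, which carries the 8mer too, rose by 0.19, and Tob2, Tusc2 and Med13 rose by 0.73, 0.72 and 0.30. Tob2 carries a 7mer-A1 site, Tusc2 a 7mer-m8 site and Med13 no 6mer match. Ksr1, Sufu and Casp9 had log2 fold changes of -0.12, 0.13 and -0.04. The calls of Igf1r and Crat ended with library totals in place of TMM (adjusted p = 0.234 and 0.285) and with limma on log2(FPKM + 1) (0.496 and 0.433, the highest of ranges from 0.00269 and 0.00264). Ppargc1b, whose intron encodes miR-378a, rose from 1.94 ± 0.114 to 2.49 ± 0.323 FPKM (edgeR adjusted p = 0.0196). That call ended without control replicate 1 (adjusted p = 0.062), control replicate 5 (0.0669) or mimic replicate 2 (0.0661), in a range from 0.00406. Among genes with the 8mer, the largest falls were in Igf1, Sgpp2, Zfp618, Cyp2s1, Atp2b4, Kif26b, Cd93 and Cpne5. Cd93, a receptor linked to phagocytosis, fell from 39.3 ± 1.99 to 9.51 ± 0.746 FPKM. Apart from Igf1 and Cd93 all had a mean under 1 FPKM in control libraries.

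Few markers of other cell types were measured. Of the endothelial list 6 genes were measured, of which 2 fell and 1 rose (2 fell and 0 rose adjusted over the list alone). The number that rose was 0, with 2 or 3 falling, without control replicate 1, 2 or 4 or mimic replicate 2, 3, 4 or 5. The median was -0.68 (camera adjusted p = 0.00898, adjusted p = 0.0782 with an estimated correlation). With no filter the camera adjusted p was 0.13, the highest of a range from 3.57e-08 with fry. Flt1 fell from 10.3 ± 0.416 to 4.04 ± 0.186 FPKM and Vwf from 1.95 ± 0.139 to 0.433 ± 0.0583. Cdh5 was at 0.0573 and 0.12 FPKM, and its call (edgeR adjusted p = 0.0461) ended in 11 of 16 alternatives, with adjusted p from 0.018 to 0.141. Of 7 border macrophage and monocyte markers 4 fell, as adjusted over the list alone (median -2.30, camera adjusted p = 0.0122, adjusted p = 0.0943 with an estimated correlation). With limma on log2(FPKM + 1) and after quantile normalization, both with another gene filter, the median was -1.14. Cbr2 fell from 10.3 ± 1.53 to 1.45 ± 0.326 FPKM. Of 5 oligodendrocyte markers 4 fell, as adjusted over the list alone (camera adjusted p = 0.375), with Mbp under 0.4 FPKM in both group means. Fewer than 5 astrocyte, neuron, fibroblast and mural, and lymphocyte and neutrophil markers were measured, too few for a test. Of these 1 of 3, 0 of 2, 1 of 2 and 1 of 3 passed, as adjusted over each list alone. Aldoc, of the astrocyte list, was at 99.6 and 80.7 FPKM in control and mimic libraries, Tagln at 0.174 and 0.433 and Cd4 at 0.229 and 0.0235. The other measured astrocyte markers were under 1 FPKM in both group means, so the level of Aldoc alone does not show astrocyte RNA.

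Of the lists kept as measures of RNA quality, the 13 mitochondrially encoded genes rose in 11 and fell in 2 (median 0.82, camera adjusted p = 6.43e-07, adjusted p = 0.20 with an estimated correlation). All genes of the mitochondrial chromosome together held 2.60% to 2.92% of counts in control and 3.44% to 3.70% in mimic libraries. mt-Cytb, mt-Nd1, mt-Nd5 and mt-Nd3 rose by 0.995, 0.91, 0.86 and 0.95 on the log2 scale, and mt-Co1 fell by 0.20. After quantile normalization mt-Co1 was at -2.12e-15, and mt-Co2, which rose by 0.12, was at -0.196. That method gives equal ranks equal values, so a gene that keeps its rank in every library cannot differ. The value for mt-Co1 therefore does not test its fall. These genes share reads with nuclear copies on chromosome 1 and are uncertain in level. Immediate early and dissociation-induced genes went both ways (9 rose and 4 fell of 15, camera adjusted p = 0.949). Jun fell by 1.77, and Nr4a1 and Ier2 rose by 1.61 and 0.90. Ribosomal protein genes were slightly lower, 22 of 30 falling and 3 rising (median -0.19, camera adjusted p = 0.0122, adjusted p = 0.624 with an estimated correlation). The number that rose was 1, with 21 to 24 falling, without control replicate 1, 2, 4 or 5 or mimic replicate 1. Rpl3, Rpl22, Rpl4 and Rpl11 fell by 0.52, 0.56, 0.27 and 0.37. The median was 0.0107 after quantile normalization (adjusted p = 0.857, the highest of a range from 6.93e-06), and these genes have many pseudogenes. The 3 lists gave the same numbers adjusted over each list alone.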

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

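All tests here except the counts of splits for changed genes and for lists with the preset correlation were chosen only after the results were seen.

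Of 308 groups of 5 libraries tested for a single library far from the others (the named genes and 4 measures per library), 16 were picked out, against 15.4 that chance would give, and 3 of these were in mimic replicate 1. In that library Sfn (4.10 FPKM, the others 0.993 to 1.54; ratio of gap to range 0.824), Mbp (0.205, the others 0.0764 to 0.101; 0.806) and Rpl3 (341, the others 324 to 329; 0.738) stood apart. In control replicate 5 they were Arg1 (15.7 FPKM, the others 19.2 to 19.9; 0.83), Oasl2 (7.32, the others 6.06 to 6.39; 0.738), Echs1 (9.11, the others 9.76 to 10; 0.717), Plin2 (57.9, the others 62.5 to 64.2; 0.73) and Zfp618 (0.0337, the others 0.0893 to 0.112; 0.712). In control replicate 2 they were H2ac7 (0.959, the others 0.453 to 0.582; 0.744) and Ccnb2 (59.4, the others 56.5 to 57.3; 0.725), in control replicate 3 Nln (6.52, the others 7.39 to 7.58; 0.819) and mt-Nd1 (1300, the others 1580 to 1690; 0.72), and in control replicate 1 Casp9 (9.63, the others 10.2 to 10.4; 0.733). In mimic replicate 3 it was Cybb (6.78, the others 5.84 to 6.07; 0.759), and in mimic replicate 2 Crat (12.9, the others 12 to 12.1; 0.863).

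Mimic replicate 1 held 93 genes at over 2 CPM and over 5 times the highest of the other libraries plus 0.2 CPM, while other libraries held 0 to 2 such genes; together they made 0.0841% of its counts. Krt8 stood at 58.63 CPM, Krt18 at 44.63, Krt7 at 37, Fn1 at 46.23, Itga3 at 44.69 and Axl at 26.79. Reads misassigned from the other 9 libraries are not the source, because a library that gave them would hold more of these genes (highest Krt8 value there 0.0615 CPM, highest Krt18 value 0), and libraries not used here were not tested. A list of 34 epithelial markers, written after some of these genes had been seen, was checked for RNA of epithelial cells. Of the 31 seen at all, 14 exceeded 5 times the highest other library plus 0.2 CPM, against 4 of 72 markers of other cell types (Fisher's exact test p = 5.31e-06). Without the 0.2 CPM these were 17 of 31 and 8 of 72, so whether most of the markers passed, as that explanation required, hung on this choice, and 11 of the 14 were among the 93 genes. Mimic replicate 1 also held 73% of the CPM sum of the fibroblast and mural list over all libraries, against 41.6% for the epithelial list, but 2 of the 11 fibroblast and mural markers seen exceeded 5 times the highest other library. Epithelial RNA and RNA of another source cannot be told apart, because the list was not independent of these genes and Fn1 and Col4a1 are made by several cell types, and RNA of another species was not tested. Only 21 of the 93 genes passed the count filter and 11 were changed.

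The count of changed genes was as high in 1 of 100 splits of the 10 libraries (the real one, 10056, with 2 as the highest of the others). The 3 lists called with an estimated correlation were reached in 1 of 100 splits (highest other 0). The other splits mix the groups, so the group difference enters the spread on each side and low numbers there were built in. They cannot exclude chance, such as a chance difference between the cultures of the 2 groups. The 15 lists called with the preset correlation were also reached in 1 of 100 splits, but the highest of the others called 14, in splits that keep part of the group difference, and only 100 of the 126 splits were drawn, so this rests on a margin of 1 list. A difference in library size is not the source, as libraries thinned to equal totals still gave 9196 changed genes. Direct repression through the seed as the main source of the falls is argued against by the share of genes with a 7mer or 8mer site that fell, 34.74%, against 36.52% of genes without a site. A weak effect on 8mer genes stays open. The culture, the day and the transfection of each group are not labelled, so they remain untested beside the mimic itself.

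The mitochondrial transcripts did not change alike. mt-Nd2 rose by 1.08 and mt-Co1 fell by 0.20 on the log2 scale, a range of 1.28 over the 13 genes, which more mitochondrial RNA of all kinds would not give. Reads divided differently between genes and their nuclear copies were checked for mt-Nd4l, mt-Nd3, mt-Co3, mt-Atp6 and mt-Co2. For these 5 genes the log2 fold change of gene and copy together differed from that of the gene by at most 0.006. Gene and copy had near-equal levels, so the way shared reads were counted may have fixed this result. The check did not cover mt-Nd2 and mt-Co1, so it cannot decide the question for the full range. A difference in the stability or processing of these transcripts may remain, and was not tested.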

How the results depend on the processing

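The alternatives limma on log2(FPKM + 1), mean FPKM of at least 1, counts divided by 4, library totals without TMM and thinning were chosen after seeing the data. No called gene of the rule and no called list was called in the other direction under any alternative, though 18 other genes were under quantile normalization. Axl, not called with a log2 fold change of 1.27, was called lower without mimic replicate 1, the only library that held it high, and ranged from -3.88 to 1.59 with each library left out. Genes with at least a 1.5-fold change numbered 4220 (1857 higher, 2363 lower) and at least 2-fold 2111 (765, 1346); with a mean FPKM of at least 5 the changed genes numbered 5849 (2940, 2909), fewer because fewer genes were tested. Changed genes, lower, numbered 3258 with limma on log2(FPKM + 1), 3253 at a pseudocount of 0.1 and 3304 with array weights, for which the cause was not tested, though these fits lack TMM. The number of gene lists called was 3 with an estimated correlation and 25 with fry, which does not compare a list with other genes. The seed-site shift of 0.0248 lost its call with adjustment for 3' UTR length and GC (0.00461) and as 5 pairs (0.0248, exact p = 0.0625, the smallest 5 pairs allow). Leaving out each library in turn gave 9711 to 9974 changed genes (4708 to 4950 higher, 4876 to 5099 lower), 15 to 17 lists, 137 to 140 called named genes of 150 and a seed-site shift of 0.0224 to 0.0295. The replicate block gave 9768 changed genes, 15 lists and 139 named genes; same-numbered libraries correlated at -0.0087 to 0.0621, and 4 of 10 correlated best with their own number, so the numbers were not taken to pair them. DESeq2 called 10186 genes; lists were not run with it. With a pseudocount of 0.1 the median log2 fold change of the genes was 0.107 and with TMM -0.0021. The list of amyloid-β degrading enzymes lost its call in 8 of 26 alternatives, the unfolded protein response in 6, ribosomal proteins in 4 and alternative activation in 2. The lists of disease-associated microglia, phagocytic receptors and interferon genes were called in all 26. At this depth the exact folds of genes near 0 in the mimic libraries cannot be given.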

Other observations

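The tests of KEGG terms and of chromosome medians were chosen after the results were seen. By camera with the preset correlation 8 of 281 terms in the deposited annotation were higher with the mimic and 35 lower. With an estimated correlation 0 passed, and 57 had an unadjusted p under 0.05. Terms that were lower included osteoclast differentiation (59 of 104 genes fell, 29 rose; adjusted p = 0.000168, adjusted p = 0.147 with an estimated correlation), the citrate cycle (20 of 29 fell; adjusted p = 0.00019, adjusted p = 0.157 with an estimated correlation), HIF-1 signalling (45 of 79 fell; adjusted p = 3e-04, adjusted p = 0.173 with an estimated correlation) and complement and coagulation (22 of 42 fell, 4 rose; adjusted p = 0.00037, adjusted p = 0.16 with an estimated correlation). Of genes chosen after their values were seen, the osteoclast protease Ctsk fell by 1.30 on the log2 scale, coagulation factor F10 by 3.05, Idh2 by 0.83 and the sialic acid receptor Cd33 by 1.66. DNA replication (24 of 35 rose, 6 fell; adjusted p = 0.000422, adjusted p = 0.376 with an estimated correlation) and RNA transport (87 of 149 rose; adjusted p = 0.00296, adjusted p = 0.402 with an estimated correlation) were higher.

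Mki67 and Top2a, expressed in dividing cells, and Spp1, Lgals3 and Apoe were chosen after their values were seen. Mki67 was at 26.5 and 33.1 FPKM and Top2a at 21.5 and 39.2 FPKM in control and mimic libraries. Spp1 (1208 to 524 FPKM), Lgals3 (673 to 268 FPKM) and Apoe (563 to 350 FPKM) were abundant in both groups.

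A gain or loss of a chromosome in one group was tested as a hypothesis formed after seeing the data. The most extreme chromosome median of relative log2 fold change was -0.0663 (chromosome 6, interval -0.119 to -0.00649), against the 0.585 expected for 3 copies in place of 2, so the medians argue against it.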
